A study of Drosophila melanogaster with 15 samples.

How the data were processed

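The samples were 15 Drosophila melanogaster RNA libraries that the labels call skeletal muscle, obtained by dissection and prepared as stranded total RNA. They fall into 5 groups of 3 libraries: 2 RNAi constructs against dpp (construct 1 and construct 2), a control RNAi group, dpp overexpression and a further group called control. dpp encodes Decapentaplegic, a secreted ligand of the BMP family, and RNAi lowers a transcript by means of a matching double-stranded RNA. Groups were taken from the sample titles, because the treatment label reads RNAi for all 15 libraries. The labels do not say that replicates came from separate animals or cultures, so the p-values measure only the spread between samples. The library codes hold a number block that is shared by both dpp RNAi groups, differs in control RNAi and is shared by dpp overexpression and control. If that block marks a batch, batch and group cannot be told apart when the dpp RNAi groups are compared with control RNAi. The same holds for their comparisons with control, whose block differs from theirs as well.

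The deposited files hold raw counts per gene symbol, as whole numbers, followed by 5 HTSeq summary lines per file. Per the submitters' processing notes, the genome build was dm3 and the tools were BWA, STAR and HTSeq; versions, the role of each aligner, the annotation and the strand setting are not stated there. Reads of overlapping genes, antisense genes and near-identical paralogs could therefore have been divided in ways that the files do not show. Of the 15682 gene symbols, 11943 matched a symbol of the dm6 annotation, 3426 matched through a synonym, 153 were ambiguous and 160 had no match. The annotation served only for current symbols, chromosome arms and gene order, and symbols are current ones, with that of the files in brackets where more than letter case differs.

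Gene counts per library, in units of 1e+06, summed to between 11.24 and 56.29: 11.24 to 18.08 with construct 1, 16.72 to 22.4 with construct 2, 31.77 to 33.29 in control RNAi, 25.54 to 56.29 with dpp overexpression and 36.81 to 53.33 in control. The HTSeq summary lines (reads not assigned to 1 gene or not aligned) made up 14.48 to 20.93% of all entries. A gene with 0 counts in a library could be present at up to 3 counts, which is 0.0533 to 0.2668 counts per 1e+06 gene counts depending on the library, without TMM factors. CPM are counts per 1e+06 gene counts scaled by TMM factors. Folds against a group with 0 counts are given as at least the fold over 3 counts summed over that group, and folds against 1 to 3 counts carry a 95% counting interval. These intervals and floors cover counting error only, since reads copied by PCR are not independent molecules. With 3 libraries against 3, the smallest p of an exact permutation test is 0.1, so single genes were tested only in a model across all genes.

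Counts were analysed in R 4.3.3 with edgeR 4.0.16. The filterByExpr function (minimum count 10) kept 10668 genes and left out 5014. TMM scaling and a quasi-likelihood fit with robust dispersions were applied to all 15 libraries at once, with 10 residual degrees of freedom. The comparisons were each dpp RNAi construct against control RNAi, dpp overexpression against control, and construct 1 against construct 2. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. A gene was called with both constructs when both comparisons called it in the same direction. Levels are means ± SD of CPM over 3 libraries, fold changes are log2 values ± SE, and log2 CPM used a prior count of 2. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the files, and matplotlib 3.10.9 drew the plots.

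Before the data were examined, 35 gene lists were fixed. They covered BMP signalling components, Dpp target genes, the activin branch, secreted signals, sarcomere proteins, oxidative phosphorylation, mitochondrially encoded genes, glycolysis with glycogen and trehalose, the citric acid cycle, lipid metabolism, amylases and maltases, ribosomal proteins, the proteasome, autophagy, heat-shock proteins, immunity, tissue stress, detoxification, extracellular matrix, circadian clock, ecdysone response, dopamine metabolism, RNA interference, growth signalling and a transgene-linked marker set. Markers of fat body, neurons, glia, haemocytes, trachea, cuticle and epidermis, digestive tract, male accessory gland and testis, ovary, and sex formed the remaining lists. The 34 lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over 102 tests. Adjusted p-values of lists come from camera; those with an estimated correlation are given beside each called list, also against control, where they were added after the data were seen. Of 25 calls, 2 held with the estimated correlation: the immune list with dpp overexpression and the cuticle list with construct 1.

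Named genes were chosen by a rule with 6 parts, fixed together with the lists: dpp; the 10 higher and 10 lower genes with the largest change among those called with both constructs; the same for dpp overexpression; up to 4 called members of each list per comparison and the 2 most abundant members of each marker list; up to 5 genes per direction called oppositely by both constructs and by overexpression; and 5 per direction between the constructs. The ranked genes had to have a given name, a mean of at least 5 CPM and no overlap between the libraries compared. Genes named outside this rule are said to be so.

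Alternatives were library totals, upper-quartile and RLE scaling, no filter, a filter of at least 5 CPM in 3 libraries, removal of mitochondrial and rRNA genes, DESeq2 1.42.0, limma-voom, non-robust dispersions, a fit of only the libraries compared, the replicate number as a block, an adjusted p under 0.01, a 2-fold minimum and the removal of each library in turn. Thinning to the smallest library total and the use of control in place of control RNAi were added after the data were seen. The pipeline was tested on simulated data in which 50 genes per fold were raised or lowered. Over the comparisons, it recovered 46 to 52% of them at 1.25-fold and 80 to 94% at 2-fold. Reads themselves, transcript isoforms and the HTSeq summary lines were not used in the comparisons.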

Results

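dpp was examined first in every group, since it checks the labels. Its level was 31.5 ± 3.02 CPM (SD, n = 3 here and in every group) in control RNAi, 32.0 ± 1.52 CPM in the libraries labelled dpp RNAi construct 1 and 31.3 ± 2.2 CPM in those labelled dpp RNAi construct 2. The log2 fold changes against control RNAi were 0.02 ± 0.12 (SE; adjusted p = 0.942, edgeR) and -0.01 ± 0.12 (adjusted p = 0.951), so a lower level of dpp was not detected under either label. Against the control libraries they were -0.07 and -0.10. With dpp overexpression the level was 66.8 ± 13.4 CPM, against 33.5 ± 1.61 CPM in control (1.00 ± 0.11, adjusted p = 1.39e-05). Because a lower level was not detected, both RNAi groups are named by their labels throughout. A direction given for them is relative to control RNAi, not to a measured loss of dpp. The libraries measure dpp summed over all cells collected. Sarcomere genes took 0.87 to 2.14% of TMM-scaled counts, so a loss limited to muscle cells would not necessarily show.

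The most abundant transcript in the 15 libraries, on average, was ninaE, the rhodopsin of outer photoreceptors, with 3.00 to 4.01% of gene counts per library. The 36 sarcomere genes together took 0.87 to 2.14% of TMM-scaled counts, a slightly different base. ninaE was chosen after its values were seen. Its level did not pass the test with construct 1 (0.11, adjusted p = 0.339), construct 2 (-0.13, adjusted p = 0.218) or dpp overexpression (-0.05, adjusted p = 0.722).

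dpp overexpression was accompanied by changes in known Dpp-responsive genes. brk, a repressor that Dpp signalling silences, fell from 15.0 ± 0.38 to 7.82 ± 0.0583 CPM (-0.94 ± 0.09, adjusted p = 1.05e-06). Dad, an inhibitory Smad induced by Dpp, rose from 74.0 ± 1.29 to 94.2 ± 3.01 CPM (0.35 ± 0.04, adjusted p = 1.24e-05). tld encodes a protease that releases Dpp from its inhibitor. It rose from 10 ± 0.9 to 25.3 ± 3.22 CPM (1.34 ± 0.10, adjusted p = 5.42e-08). sog, which encodes that inhibitor, fell (-0.27 ± 0.05, adjusted p = 0.0012). aos, an inhibitor of EGF receptor signalling, fell from 38.3 ± 0.626 to 24.6 ± 0.236 CPM (-0.64 ± 0.07). Of 17 tested Dpp target genes, 1 was higher, 7 were lower and 9 were not called (1 higher and 8 lower adjusted over the list alone, list adjusted p = 0.15). Among 22 BMP signalling components, 5 were higher, 5 lower and 12 not called (6 and 6 adjusted over the list alone, list adjusted p = 0.747). In the libraries labelled dpp RNAi, brk and Dad were not called with either construct (brk -0.06 and 0.10; Dad 0.04 and -0.02), a pair of results chosen after the values were seen. Against the control libraries Dad was lower with both constructs (-0.19, adjusted p = 0.00612; -0.25, adjusted p = 0.000468), and brk was higher with construct 2 (0.31, adjusted p = 0.0143) and not called with construct 1 (0.16). In control RNAi itself, Dad was lower than in control (-0.23, adjusted p = 0.000538).

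**Figure D1:**
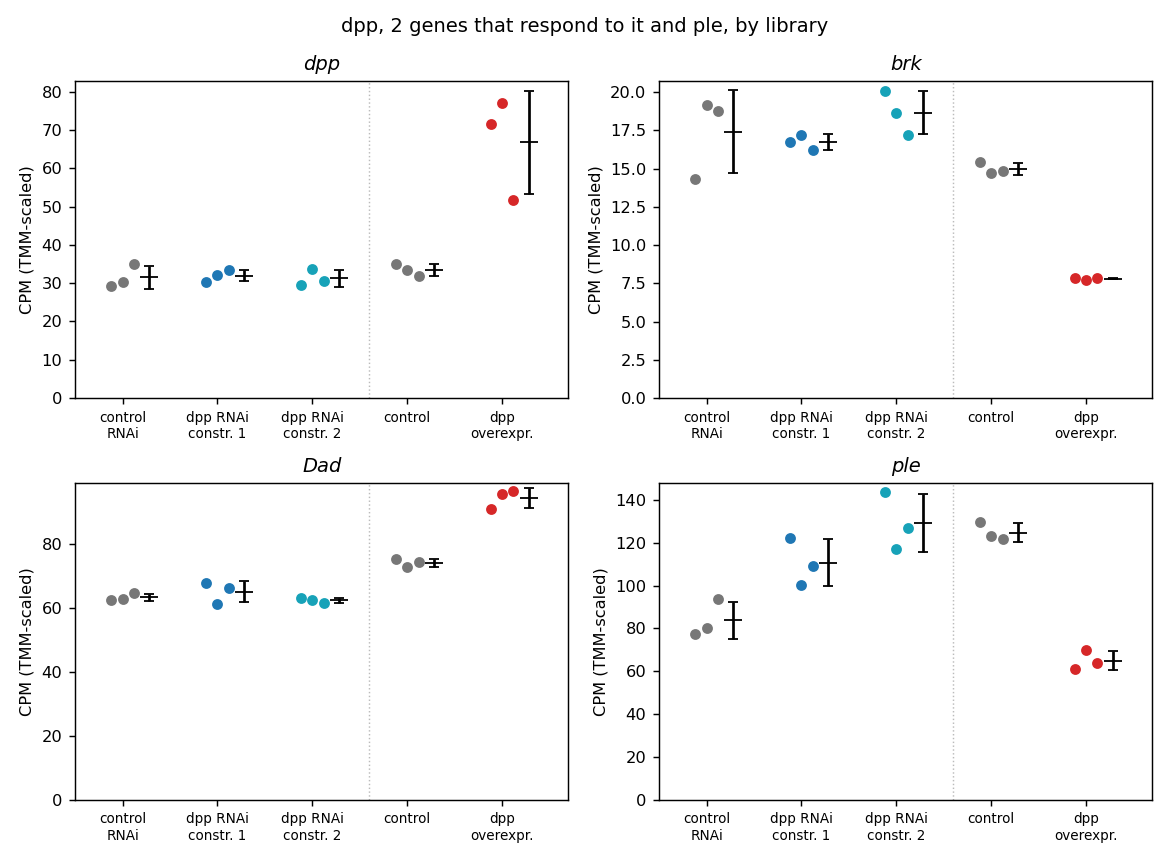
Levels of dpp, brk, Dad and ple (CPM, TMM-scaled, y axis from 0) in the 15 libraries of 5 groups; each point is a library, the black mark is the mean with its SD over 3 libraries, and a dotted line parts the RNAi groups from control and overexpression. dpp lies near 32 CPM in all groups but overexpression, with a mean of 66.8 CPM, and ple is lowest with overexpression, at a mean of 65 CPM.

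Humoral immune genes were among the largest rises with dpp overexpression. Drs, which encodes the antifungal peptide drosomycin, rose from 5.62 ± 0.899 to 791 ± 116 CPM (141-fold; 7.13 ± 0.13, adjusted p = 4.2e-13). The antibacterial peptide genes Dro and Dpt rose from 4.03 ± 1.05 to 558 ± 117 CPM (7.11 ± 0.19) and from 7.27 ± 3.9 to 484 ± 59.5 CPM (6.07 ± 0.34). AttC rose from 21.7 ± 7.81 to 859 ± 180 CPM (5.31 ± 0.43). edin, an infection-induced gene, rose from 0.218 ± 0.0829 to 50.7 ± 10.3 CPM (7.89 ± 0.30, adjusted p = 2.94e-13). PGRP-SA, a receptor for bacterial peptidoglycan, rose from 11.1 ± 0.753 to 57.2 ± 7.43 CPM (2.37 ± 0.09). Of 42 tested immune genes, 31 were higher, 3 lower and 8 not called (32 and 3 adjusted over the list alone), with a median log2 fold change of 1.47 (list adjusted p = 1.68e-45, adjusted p = 0.0216 with an estimated correlation). Drsl4 (dro4) fell (-1.20 ± 0.09). Attacin and cecropin genes are near-identical copies, so counts could have been divided among them.

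**Figure D2:**
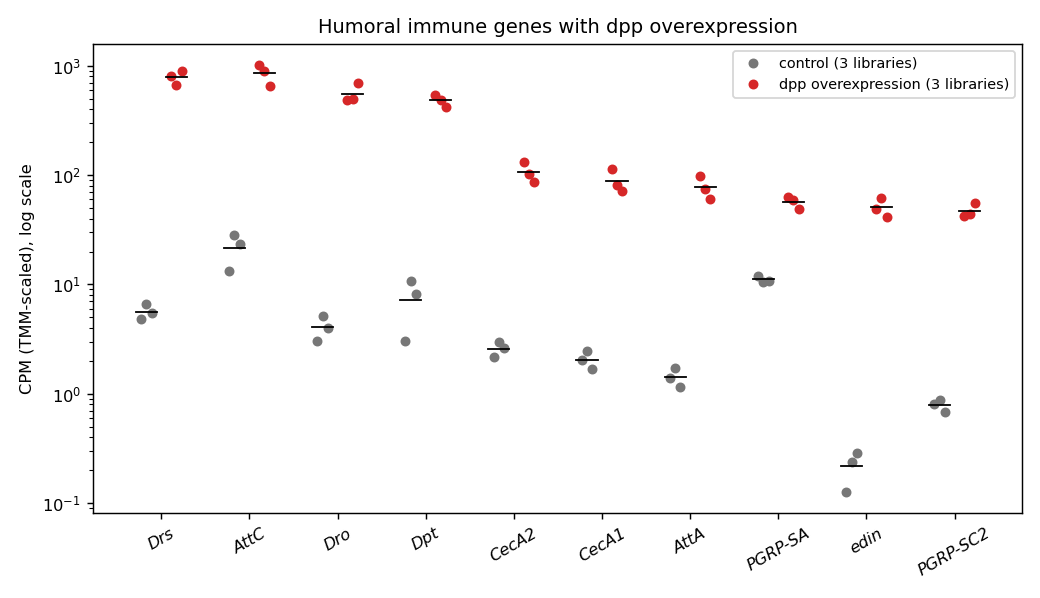
Levels of 10 immune genes (CPM, TMM-scaled, log y axis) in the 3 control (grey) and 3 dpp overexpression (red) libraries; points are libraries and black lines are group means. Overexpression lies above control for each of the 10 genes, from 5.16-fold for PGRP-SA to 237-fold for edin. The 10 genes were picked from those called higher, so this direction holds by construction. Of the 42 tested immune genes, 3 were called lower.

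FASN2 (v(2)k05816), a fatty acid synthase gene, rose from 3.76 ± 0.455 to 38.3 ± 5.66 CPM (3.34 ± 0.16, adjusted p = 2.55e-09), and desat1, a fatty acid desaturase gene, rose (0.54 ± 0.07). CG10924 fell (-1.39 ± 0.11). Of 28 lipid metabolism and starvation genes, 11 were higher, 12 lower and 5 not called (11 and 14 adjusted over the list alone, list adjusted p = 0.957). Tps1, the trehalose synthesis gene, rose from 460 ± 25 to 975 ± 165 CPM (1.08 ± 0.10), and Pgm1 (Pgm) rose (0.53 ± 0.05). The hexokinase gene Hex-C rose (0.68 ± 0.09). Among 24 glycolysis, glycogen and trehalose genes 9 were higher, 1 was lower and 14 were not called, with the same counts adjusted over the list alone (list adjusted p = 0.0191, adjusted p = 0.745 with an estimated correlation). Ribosomal protein genes were higher in 41 of 85 cases, lower in 2 and not called in 42 (51 and 3 adjusted over the list alone, median 0.18, adjusted p = 6.06e-05, adjusted p = 0.867 with an estimated correlation). RpL32 rose by 0.37 ± 0.06. The stress-linked translation inhibitor gene Thor rose from 124 ± 0.951 to 176 ± 3.72 CPM (0.50 ± 0.05). Of 19 growth signalling genes 8 were higher, 1 was lower and 10 were not called, with the same counts adjusted over the list alone (list adjusted p = 0.144). Of 9 amylase and maltase genes, 2 were higher and 7 not called (1 higher adjusted over the list alone, adjusted p = 0.324).

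Of the list of dopamine and tyrosine metabolism, the called genes were lower with dpp overexpression. ple, which encodes tyrosine hydroxylase, fell from 125 ± 4.33 to 65 ± 4.53 CPM (-0.94 ± 0.09, adjusted p = 1.07e-06). Dat, a symbol that is ambiguous in the annotation, so that its function is left open, fell from 206 ± 10 to 131 ± 12.7 CPM (-0.65 ± 0.06), and e (ebony, a beta-alanyl-dopamine synthase) fell from 63.0 ± 4.61 to 36.5 ± 4.53 CPM (-0.78 ± 0.09). Pu, which supplies the cofactor of tyrosine hydroxylase, fell (-0.32 ± 0.05). Ddc, the dopa decarboxylase gene, was chosen after its values were seen and was not called (-0.15 ± 0.07, adjusted p = 0.0938). Of 17 genes on the dopamine and tyrosine list none was higher, 5 were lower and 12 were not called, and the same held adjusted over the list alone (median -0.13, list adjusted p = 0.0213, adjusted p = 0.249 with an estimated correlation). Cuticle genes and markers of body parts moved in the same comparison, as given next. A different make-up of the tissue is therefore not separated from the fall of these genes.

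Of the cuticle genes called with dpp overexpression, most were lower. Lcp65Ag2, a larval cuticle protein gene, fell from 9.21 ± 0.452 to 1.43 ± 0.0905 CPM (-2.67 ± 0.14, adjusted p = 9.31e-10), and Cpr65Au from 366 ± 8.37 to 119 ± 4.91 CPM (-1.62 ± 0.06). Of 51 tested cuticle and epidermis genes, 2 were higher, 20 lower and 29 not called (2 and 21 adjusted over the list alone, median -0.32, adjusted p = 0.000339, adjusted p = 0.302 with an estimated correlation). Obp56a, an odorant-binding protein gene, fell from 64.1 ± 11.3 to 10.5 ± 2.74 CPM (-2.62 ± 0.28, adjusted p = 4.51e-05). Markers of body parts moved in the same comparison, and were chosen after values were seen: Antp, the thoracic Hox gene, was lower (-0.97, adjusted p = 0.00854), as were the antennal genes Pbprp5 (-1.59) and Os-E (-1.57), and the CheA and CheB genes had a median of -1.35. A different make-up of the tissue is thus not separated from these changes. The cytochrome P450 genes Cyp4ac2 and Cyp6a2 fell (-2.13 ± 0.11 and -1.92 ± 0.04). Cyp304a1 rose from 0.577 ± 0.282 to 51.9 ± 26.2 CPM (6.53 ± 0.57, adjusted p = 1.32e-06). Of 34 detoxification genes, 9 were higher, 12 lower and 13 not called, with the same counts adjusted over the list alone (adjusted p = 0.637). Dcr-1, the dicer of microRNA processing, rose from 33.6 ± 0.79 to 67.4 ± 0.604 CPM (1.01 ± 0.05). The RNA interference list of 8 had 1 higher, 1 lower and 6 not called, also adjusted over the list alone (adjusted p = 0.349). The eye colour gene w, which many transgenes carry, rose from 12.6 ± 0.719 to 42.5 ± 2.72 CPM (1.75 ± 0.08). It was the 1 called member of the 3 in the transgene-linked list, with the same count adjusted over the list alone (adjusted p = 0.00307, adjusted p = 0.246 with an estimated correlation), and that list's p was 0.0679 when only the libraries compared were fitted.

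Most other lists were not called with dpp overexpression. Sarcomere genes were higher in 6 of 36 cases and lower in 4, with the same counts adjusted over the list alone (median 0.00, adjusted p = 0.853), among them Act57B at 0.77 ± 0.09. Of 57 oxidative phosphorylation genes 1 was higher and 56 were not called (none adjusted over the list alone, adjusted p = 0.853). Of 18 citric acid cycle genes 3 were higher and 3 lower (3 and 5 adjusted over the list alone, adjusted p = 0.9). Secreted signals had 5 higher and 6 lower of 31 (7 and 7 adjusted over the list alone, adjusted p = 0.896). bnl, an FGF ligand gene, rose (0.66 ± 0.08) and CCHa2, a nutrient-linked peptide hormone gene, fell from 341 ± 20 to 184 ± 1.86 CPM (-0.90 ± 0.06). The activin branch had 1 lower of 8, also adjusted over the list alone (adjusted p = 0.711). Proteasome genes had 3 lower of 32 (2 adjusted over the list alone, adjusted p = 0.168). Autophagy genes had 7 higher and 1 lower of 25, the same adjusted over the list alone (adjusted p = 0.397). Heat-shock genes had 2 higher and 1 lower of 22 (1 and 1 adjusted over the list alone, adjusted p = 0.574). Tissue stress genes had 4 higher and 4 lower of 19 (5 and 4 adjusted over the list alone, adjusted p = 0.966), with the transcription factor gene Ets21C at 1.72 ± 0.18. Adjusted over the list alone and over all genes alike, extracellular matrix genes had 2 higher and 2 lower of 18 (adjusted p = 0.9), clock genes 1 and 2 of 11 (adjusted p = 0.556) and ecdysone response genes 2 and 1 of 16 (adjusted p = 0.771).

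Among marker lists, fat body markers had 6 higher and 1 lower of 16 with dpp overexpression (7 and 1 adjusted over the list alone, adjusted p = 0.238). The larval storage protein genes Lsp1gamma and Lsp1alpha moved in opposite directions (5.31 ± 0.37 and -4.17 ± 0.42). Neuronal markers had 1 higher and 1 lower of 18 (none adjusted over the list alone, adjusted p = 0.896). With equal counts adjusted over the list alone, glia had 3 lower of 8 (adjusted p = 0.646), haemocytes 3 higher and 1 lower of 12 (adjusted p = 0.747), trachea 3 lower of 8 (adjusted p = 0.349), ovary 1 higher and 1 lower of 9 (adjusted p = 0.88) and sex markers 2 higher of 10 (adjusted p = 0.535). Digestive tract markers had 2 higher and 1 lower of 18 (1 and 1 adjusted over the list alone, adjusted p = 0.474). None of 7 male accessory gland and testis markers was called, nor adjusted over the list alone (adjusted p = 0.635). The median, mean and test of a list differed in sign for BMP components, sarcomere, lipid, tissue stress and detoxification genes, all of them not called.

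In all, dpp overexpression and control differed in 3156 genes, 1426 higher and 1730 lower, by edgeR's quasi-likelihood test. Of these, 664 changed at least 2-fold (320 higher, 344 lower). The 3 libraries of each group did not overlap for 45.7% of tested genes, where chance gives 10%.

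Larval cuticle genes, together with the CheA and CheB genes described further on, were among those that differed most between the libraries labelled dpp RNAi and control RNAi. Lcp1, a larval cuticle protein gene, was at 0.115 ± 0.0632 CPM in control RNAi, 65.3 ± 8.97 CPM with construct 1 and 43.7 ± 12.6 CPM with construct 2 (9.09 ± 0.76, adjusted p = 7.32e-09; 8.51 ± 0.76, adjusted p = 6.41e-09). Lcp3 rose from 0.334 ± 0.123 to 48.6 ± 5.22 and 16.8 ± 4.2 CPM (7.16 ± 0.36 and 5.62 ± 0.37). Lcp2 had 0 counts in control RNAi and was at least 577-fold higher with construct 1 and at least 329-fold higher with construct 2. Cpr78E had 3 counts in control RNAi and was 246-fold higher with construct 1 (95% counting interval 83.6 to 1200) and 196-fold higher with construct 2 (66.5 to 955). Fbp1, the receptor gene of larval fat body storage proteins, rose from 0.219 ± 0.0896 to 2.83 ± 0.699 and 2.16 ± 0.591 CPM (3.63 ± 0.36 and 3.26 ± 0.36). Against the control libraries, Lcp1 was higher by 8.25 and 7.67, Lcp3 by 8.20 and 6.65, and Fbp1 by 2.92 and 2.55.

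Of the 51 tested cuticle and epidermis genes, 20 were higher, 4 lower and 27 not called with construct 1, with the same counts adjusted over the list alone (median 0.38, adjusted p = 7.3e-13, adjusted p = 0.0216 with an estimated correlation). With construct 2 the counts were 15, 7 and 29 (16 and 8 adjusted over the list alone, median 0.18, adjusted p = 2.46e-05, adjusted p = 0.246 with an estimated correlation). Against the control libraries the list's adjusted p was 3.76e-09 and 0.000137 (adjusted p = 0.027 and 0.234 with an estimated correlation). retinin, a corneal lens protein gene, fell from 568 ± 37.2 to 277 ± 8.54 and 265 ± 12.7 CPM (-1.04 ± 0.14, adjusted p = 0.000192; -1.10 ± 0.14, adjusted p = 5.35e-05; against control -1.10 and -1.17). The protease inhibitor gene Spn55B (Spn6) fell from 31.1 ± 1.74 to 16.1 ± 1.44 and 15.8 ± 0.659 CPM (-0.95 ± 0.08 and -0.98 ± 0.08; against control -0.72 and -0.76).

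Muscle structural genes were higher under both labels than in control RNAi, and control RNAi stood apart from the other 4 groups in them. Act79B, a muscle actin gene, was at 38.6 ± 1.48 CPM in control RNAi, 423 ± 161 and 448 ± 133 CPM with the constructs, 429 ± 48.5 CPM in control and 511 CPM with overexpression (3.45 ± 0.31, adjusted p = 6.8e-05; 3.54 ± 0.31, adjusted p = 2.13e-05; against control -0.02 and 0.06). Mlp84B, which encodes a muscle LIM protein, rose from 96.5 ± 3.87 to 452 ± 140 and 503 ± 102 CPM, with 479 ± 51.1 CPM in control. Of 36 sarcomere genes, 27 were higher, 1 lower and 8 not called with construct 1 (27 and 2 adjusted over the list alone, median 1.09, adjusted p = 1.12e-23, adjusted p = 0.302 with an estimated correlation). With construct 2, 26 were higher, 1 lower and 9 not called (26 and 2 adjusted over the list alone, median 1.10, adjusted p = 9.45e-17, adjusted p = 0.437 with an estimated correlation). Against control the medians were 0.05 and 0.12 (list adjusted p = 0.736 and 0.565), and control RNAi was lower than control by a median of -1.02, with 27 genes lower. The small heat-shock gene l(2)efl, expressed in muscle, followed the same levels: 16.1 ± 0.757 CPM in control RNAi, 72.0 ± 18.6 and 88.4 ± 18.6 CPM with the constructs and 94.2 ± 6.27 CPM in control.

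**Figure D3:**
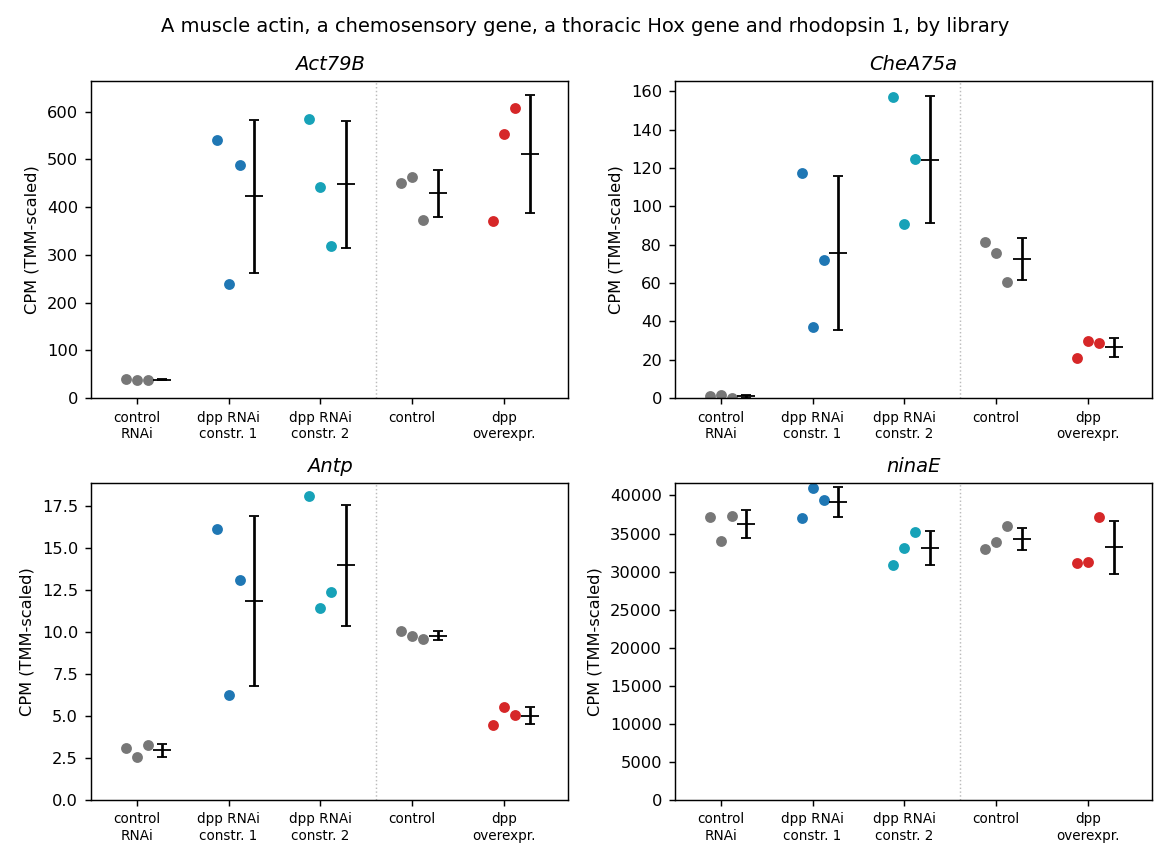
Levels of Act79B, CheA75a, Antp and ninaE (CPM, TMM-scaled, y axis from 0) in the 15 libraries of 5 groups; points are libraries, black marks are means with SD over 3 libraries, and a dotted line parts the RNAi groups from control and overexpression. Control RNAi is lowest for Act79B (mean 38.6 CPM) and for Antp (mean 2.96 CPM), no group stands apart for ninaE, and Antp was chosen after values were seen.

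The CheA and CheB genes, which encode lipid-binding proteins of taste hairs, showed the same pattern and were chosen after their values were seen. Summed over 20 genes, they took 11.9 to 21.0 CPM in the control RNAi libraries, 161 to 465 CPM with construct 1, 374 to 620 CPM with construct 2, 232 to 317 CPM in control and 94.0 to 133 CPM with overexpression. All 20 were called higher with each construct. Against control 0 were called higher with construct 1 and 8 with construct 2. CheA7a was at 1.02 ± 0.871 CPM in control RNAi, 58.6 ± 30.6 CPM with construct 1, 101 ± 23.7 CPM with construct 2 and 52.1 ± 8.79 CPM in control.

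Genes of mitochondrial respiration were higher under both labels, in the same comparisons in which sarcomere genes were higher (medians 1.09 and 1.10), so a different share of muscle is not separated from this rise. Of 57 tested oxidative phosphorylation genes, 54 were higher, none lower and 3 not called with each construct (55 adjusted over the list alone), with medians of 0.53 (adjusted p = 4.29e-34, adjusted p = 0.437 with an estimated correlation) and 0.56 (adjusted p = 2.58e-23, adjusted p = 0.493 with an estimated correlation). The complex I genes ND-B17 (l(2)35Di) and ND-51 (CG9140) rose from 56.5 ± 3.07 to 93.5 ± 2.67 and 91.7 ± 7.66 CPM, and from 331 ± 14.6 to 527 ± 61.4 and 561 ± 61.8 CPM. Against control, ND-B17 was higher by 0.36 and 0.33 (adjusted p = 0.00156 and 0.00173) and ND-51 was not called (0.04 and 0.13). The list's adjusted p was 0.0849 and 0.0862. Citric acid cycle genes had 11 higher, 3 lower and 4 not called of 18 with construct 1 (13 and 3 adjusted over the list alone, adjusted p = 0.00272, adjusted p = 0.745 with an estimated correlation) and 12, 1 and 5 with construct 2 (14 and 1 adjusted over the list alone, adjusted p = 0.000459, adjusted p = 0.649 with an estimated correlation). Against control the list's adjusted p was 0.445 and 0.0862. The succinate dehydrogenase gene SdhA rose from 349 ± 6.26 to 606 ± 107 and 629 ± 88.1 CPM (control 593 ± 23.5 CPM; 0.03 and 0.09 against control). None of the 37 mitochondrially encoded genes in the files passed the filter. Of 24 glycolysis, glycogen and trehalose genes, 8 were higher and 1 lower with construct 1, the same adjusted over the list alone (adjusted p = 0.306), and 9 and 1 with construct 2 (10 and 1 adjusted over the list alone, adjusted p = 0.0947). Pgk, the phosphoglycerate kinase gene, rose with both (0.36 ± 0.05 and 0.37 ± 0.05; against control 0.35 and 0.36).

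Immune genes were called higher in 14 of 42 cases with construct 1 and in 23 with construct 2. BomBc2 (CG15067), a Toll-dependent secreted peptide gene, rose from 394 ± 28.3 to 649 ± 82.2 and 682 ± 38 CPM (0.72 ± 0.09 and 0.79 ± 0.09; against control 0.59 and 0.66). Dro rose from 3.96 ± 0.314 to 10.9 ± 1.49 and 11.8 ± 1.68 CPM (1.47 ± 0.23 and 1.58 ± 0.22; against control 1.44 and 1.55). Of 42 genes, 14 were higher, 1 lower and 27 not called with construct 1 (15 and 1 adjusted over the list alone, median 0.38, adjusted p = 0.000886, adjusted p = 0.745 with an estimated correlation) and 23, 0 and 19 with construct 2 (24 and 0 adjusted over the list alone, median 0.65, adjusted p = 4.34e-07, adjusted p = 0.493 with an estimated correlation). Against control the list's adjusted p was 0.0104 and 3.88e-06, also higher (adjusted p = 0.813 and 0.598 with an estimated correlation). Fat body markers, given further on, were higher against control with both constructs as well, though not called against control RNAi. A different make-up of the tissue is thus not separated from the immune rise against control.

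The list of dopamine and tyrosine metabolism was not called under either label, and single members moved in both directions. ple rose from 83.7 ± 8.62 to 111 ± 11 and 129 ± 13.5 CPM (0.41 ± 0.09, adjusted p = 0.0039; 0.63 ± 0.09, adjusted p = 7.69e-05). Against control it was not called (-0.17, adjusted p = 0.182; 0.05, adjusted p = 0.682). Dat, an ambiguous symbol, rose with both constructs (0.61 ± 0.06 and 0.62 ± 0.06) and fell against control (-0.22, adjusted p = 0.0175; -0.21, adjusted p = 0.0148). DopEcR, a receptor gene for dopamine and ecdysone, fell from 573 ± 16 to 478 ± 17.3 and 398 ± 31.3 CPM (-0.26 ± 0.07 and -0.53 ± 0.07), with 444 ± 11.2 CPM in control. Of 17 genes on the list, 4 were higher and 1 lower with construct 1 (adjusted p = 0.853) and 6 and 5 with construct 2 (adjusted p = 0.556), the same adjusted over the list alone.

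Several lists were lower under the dpp RNAi labels. Of 8 genes of the activin branch, 6 were lower and 2 not called with construct 1 (adjusted p = 0.00894, adjusted p = 0.493 with an estimated correlation) and 5 and 3 with construct 2 (adjusted p = 0.0149, adjusted p = 0.493 with an estimated correlation), with the same counts adjusted over the list alone. The ligand gene Actbeta fell from 135 ± 7.03 to 110 ± 1.71 and 96.0 ± 7.58 CPM (-0.29 ± 0.06 and -0.49 ± 0.06; not called against control, 0.06 and -0.14). Against control the list was not called (adjusted p = 0.758 and 0.966). Neuronal markers had 6 lower and 12 not called of 18 with construct 1 (9 lower adjusted over the list alone, median -0.21, adjusted p = 0.0177, adjusted p = 0.867 with an estimated correlation). With construct 2, 1 was higher, 12 lower and 5 not called (1 and 13 adjusted over the list alone, median -0.36, adjusted p = 0.00322, adjusted p = 0.867 with an estimated correlation). Against control this list was higher (adjusted p = 4.91e-06 and 0.00608, adjusted p = 0.708 and 0.813 with an estimated correlation), a reversed direction. Lipid metabolism and starvation genes had 8 lower and 20 not called of 28 with construct 1, the same adjusted over the list alone (adjusted p = 0.000825, adjusted p = 0.745 with an estimated correlation), and 4 higher, 9 lower and 15 not called with construct 2, again the same (adjusted p = 0.0626). Against control the list was higher with both (adjusted p = 5.3e-05 each, adjusted p = 0.659 each with an estimated correlation): desat1 was at 4620 ± 357 CPM in control RNAi, 3196 ± 285 and 3326 ± 75.4 CPM with the constructs and 1650 ± 70.9 CPM in control. Fat body markers were higher against control too, so a different make-up of the tissue is not separated from this.

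Cyp4e3, a cytochrome P450 gene, fell from 461 ± 22.1 to 207 ± 27.4 and 124 ± 12.9 CPM (-1.16 ± 0.17, adjusted p = 0.000461; -1.90 ± 0.17, adjusted p = 9.33e-06), yet control was at 46.9 ± 3.75 CPM, so that against control it was higher (2.14 and 1.40). Myc (dm), a growth-promoting transcription factor gene, fell from 86.5 ± 7.37 to 53.7 ± 6.42 and 58.1 ± 3.58 CPM (-0.68 ± 0.08 and -0.57 ± 0.08; against control 0.41 and 0.52). Growth signalling genes had 6 lower of 19 with construct 1 (7 adjusted over the list alone, adjusted p = 0.157) and 5 higher and 7 lower with construct 2 (6 and 8 adjusted over the list alone, adjusted p = 0.349). Clock genes had 3 lower of 11 with construct 1 (5 adjusted over the list alone, adjusted p = 0.0454, 0.0812 when only the libraries compared were fitted; adjusted p = 0.437 with an estimated correlation; against control adjusted p = 0.13, higher) and 1 higher and 3 lower with construct 2, the same adjusted over the list alone (adjusted p = 0.275). With the same counts adjusted over the list alone, ecdysone response genes had 1 higher and 6 lower of 16 with construct 1 (adjusted p = 0.324) and 3 and 7 with construct 2 (adjusted p = 0.293).

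Detoxification genes had 5 higher, 7 lower and 22 not called of 34 with construct 1 (6 and 7 adjusted over the list alone, adjusted p = 0.114). With construct 2 they had 15, 4 and 15 (16 and 4 adjusted over the list alone, median 0.18, adjusted p = 0.0191, adjusted p = 0.867 with an estimated correlation; 0.0532 when only the libraries compared were fitted; against control adjusted p = 2.73e-08, also higher, and adjusted p = 0.461 with an estimated correlation). The glutathione transferase gene GstD1 rose from 267 ± 8.46 to 358 ± 41.5 and 469 ± 40 CPM, with 390 ± 19.7 CPM in control. Amylases and maltases had 2 higher and 7 not called of 9 with construct 1 (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.732) and 7 higher, 1 lower and 1 not called with construct 2, the same adjusted over the list alone (median 0.70, adjusted p = 0.0468, adjusted p = 0.649 with an estimated correlation; against control adjusted p = 0.0307, and adjusted p = 0.625 with an estimated correlation). Sex markers had 1 higher and 3 lower of 10 with construct 1 (adjusted p = 0.628) and 5 lower and 5 not called with construct 2 (median -0.34, adjusted p = 0.0468, adjusted p = 0.493 with an estimated correlation; 0.0554 after thinning; against control adjusted p = 0.295), the same adjusted over the list alone. Extracellular matrix genes had 1 higher and 1 lower of 18 with construct 1 (1 lower adjusted over the list alone, adjusted p = 0.877) and 8 and 3 with construct 2 (9 and 4 adjusted over the list alone, adjusted p = 0.349, 0.000162 when only the libraries compared were fitted). Haemocyte markers had 1 higher and 2 lower of 12 (adjusted p = 0.877) and 5 and 1 (adjusted p = 0.168, 7.26e-07 when only the libraries compared were fitted), the same adjusted over the list alone.

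The remaining lists were not called with either construct. BMP signalling components had 1 higher and 7 lower of 22 with construct 1 (4 and 7 adjusted over the list alone, adjusted p = 0.505) and 7 and 6 with construct 2, the same adjusted over the list alone (adjusted p = 0.853). Dpp target genes had 1 higher and 2 lower of 17 (1 and 0 adjusted over the list alone, adjusted p = 0.853) and 5 and 1, the same adjusted over the list alone (adjusted p = 0.747). Secreted signals had 1 higher and 4 lower of 31 (adjusted p = 0.218) and 5 and 7 (adjusted p = 0.909), the same adjusted over the list alone. Ribosomal protein genes had 17 higher and 3 lower of 85, the same adjusted over the list alone (adjusted p = 0.102). With construct 2 the counts were 14 and 6 (12 and 6 adjusted over the list alone, adjusted p = 0.853). Against control they were higher (adjusted p = 2.73e-08 and 0.000595, adjusted p = 0.813 and 0.866 with an estimated correlation). Proteasome genes had 1 higher and 2 lower of 32 (adjusted p = 0.933) and 11 and 1 (adjusted p = 0.157), the same adjusted over the list alone. Autophagy genes had 1 higher and 3 lower of 25 (0 and 2 adjusted over the list alone, adjusted p = 0.558) and 2 and 4 (2 and 2 adjusted over the list alone, adjusted p = 0.909). Heat-shock genes had 3 higher and 5 lower of 22 (adjusted p = 0.351) and 3 and 7 (adjusted p = 0.558), the same adjusted over the list alone. Tissue stress genes had 2 higher and 4 lower of 19, the same adjusted over the list alone (adjusted p = 0.877), and 1 and 5 (1 and 4 adjusted over the list alone, adjusted p = 0.558). RNA interference genes had 2 lower of 8 (2 higher and 2 lower adjusted over the list alone, adjusted p = 0.604) and 1 higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.877). AGO1, an Argonaute gene of microRNA silencing, fell with both (-0.38 ± 0.07 and -0.40 ± 0.07; against control 0.27 and 0.26). The transgene-linked list had 3 lower of 3 (adjusted p = 0.0912) and 2 lower (adjusted p = 0.184), the same adjusted over the list alone, with w at -0.38 ± 0.09 and -0.56 ± 0.09.

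Of the marker lists not yet given, fat body had 3 higher and 5 lower of 16 with construct 1 (3 and 6 adjusted over the list alone, adjusted p = 0.909) and 3 and 3 with construct 2, the same adjusted over the list alone (adjusted p = 0.853). Against control it was higher (adjusted p = 8.78e-06 and 2.12e-05, adjusted p = 0.0149 each with an estimated correlation). Glia had 2 higher and 4 lower of 8 (2 and 5 adjusted over the list alone, adjusted p = 0.217) and 2 and 1 (2 and 0 adjusted over the list alone, adjusted p = 0.558). Trachea had 1 lower of 8 (adjusted p = 0.941) and 3 higher and 1 lower (adjusted p = 0.604), the same adjusted over the list alone. Digestive tract markers had 1 higher and 5 lower of 18 (1 and 6 adjusted over the list alone, adjusted p = 0.418) and 8 and 6 (8 and 7 adjusted over the list alone, adjusted p = 0.877). No male accessory gland and testis marker of 7 was called, nor adjusted over the list alone (adjusted p = 0.873 and 0.877). Ovary markers had 2 lower of 9 with each construct, the same adjusted over the list alone (adjusted p = 0.531 and 0.316). The median, mean and test differed in sign, in lists not called, for Dpp targets, amylases, proteasome, tissue stress, dopamine, growth, fat body and haemocyte genes with construct 1 and for autophagy, dopamine, RNA interference and digestive tract genes with construct 2.

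By edgeR's test 2744 genes differed between construct 1 and control RNAi (1395 higher, 1349 lower) and 4406 between construct 2 and control RNAi (2244 higher, 2162 lower). At least 2-fold changes made up 444 and 535 of them. Libraries did not overlap for 41.9% and 53.5% of tested genes, where chance gives 10%. Both constructs called 1093 genes higher and 936 lower (2029 in all), where independent lists would share 293.4 and 273.4. Only 48 genes were called in opposite directions. Over 50 simulations of unchanged groups against a shared control RNAi group, which was simulated as well, no gene was called with both constructs. Across genes, which are not independent replicates, the log2 fold changes of the constructs correlated at Pearson r = 0.783 and Spearman rho = 0.662, against simulated values of 0.362 (0.274 to 0.445) and 0.378 (0.353 to 0.405). Their covariance was 0.377, against a simulated 0.0222 (0.0165 to 0.0309), a difference of 0.355. The simulations drew control RNAi and both constructs from the same means, so control RNAi could depart from them only by the spread between libraries. They therefore cannot tell how much of the overlap or of the excess comes from control RNAi standing apart as a group. Since the 3 control RNAi libraries cannot be divided into parts of at least 2, part of the excess may come from the shared controls.

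Control RNAi and control differed in 4823 genes (2234 higher, 2589 lower). Of the 2029 genes called with both constructs, 348 were called in the same direction by both against control (186 higher, 162 lower), 172 in the other direction and 1509 in neither. Cuticle genes (Lcp1, Lcp3), immune genes (BomBc2, Dro), Pgk, retinin and Spn55B were among the 348, and Act79B, Mlp84B, SdhA, ple and CheA7a were not called against control with either construct. In all 4 comparisons, of each construct with each of 2 control groups, 51 genes were called in 1 direction at 2-fold or more, 45 of them higher. Both control groups differ in code block from the dpp RNAi groups, so a batch is not separated from these calls either.

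**Figure D4:**
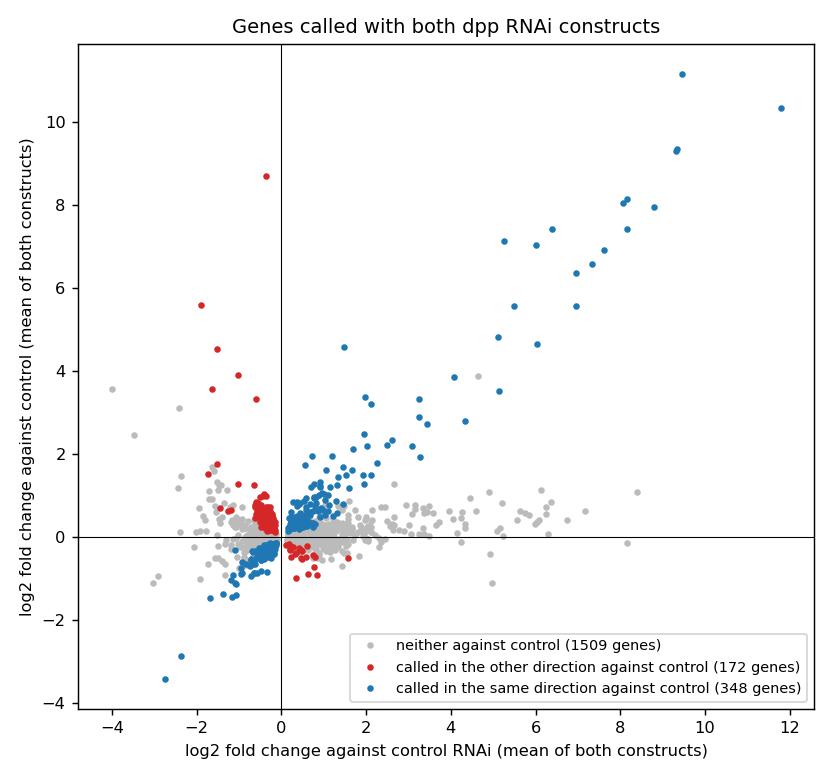
Mean log2 fold change of both dpp RNAi groups against control RNAi (x axis) and against control (y axis) for the 2029 genes called with both constructs against control RNAi; each point is a gene. The 348 blue genes were called in the same direction against control, the 172 red ones in the other direction, and the 1509 grey ones in neither.

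Opposite changes under the dpp RNAi labels and with overexpression were found for 403 genes. Of these, 273 were higher with both constructs and lower with overexpression, where 177.2 would be shared by independent lists (Fisher's exact test, two-sided, odds ratio 1.85, p = 4.01e-15, adjusted p = 6.42e-15 over 8 overlaps tested). The other 130 were lower with both constructs and higher with overexpression, where 125.1 would be shared (exact p = 0.615, adjusted p = 0.615). Genes higher in both settings numbered 107, below the 146.1 of independent lists (odds ratio 0.679, exact p = 0.00017, adjusted p = 0.000227). Lower in both were 158 genes (151.8 for independent lists, exact p = 0.577, adjusted p = 0.615). Genes are not independent replicates, so the p-values of these overlaps do not measure the spread between libraries. Obp56a was higher with the constructs (2.97 ± 0.31 and 4.20 ± 0.30) and lower with overexpression, but against control it was at -0.02 with construct 1 and 1.20 with construct 2. CG1979 fell with the constructs (-1.31 ± 0.19 and -1.23 ± 0.18) and rose with overexpression (2.22 ± 0.17), but against control it was higher with both (0.60 and 0.68). Cpr65Au was higher with both constructs against control RNAi (0.38 and 0.49) and against control (0.19 and 0.31), and lower with overexpression. Across genes the mean change of both constructs correlated with that of overexpression at r = -0.084 and rho = -0.088, within the simulated range of r for unchanged groups (-0.102 to 0.0557). With control in place of control RNAi, and so shared by both comparisons, the values were r = 0.154 and rho = 0.064. Some markers of body parts, chosen after values were seen, went the opposite way as well. Antp was at 2.02 and 2.23 with the constructs and -0.97 with overexpression. The Hox gene Ubx was at 3.69, 4.23 and -1.45. The 20 CheA and CheB genes, higher with both constructs, had a median of -1.35 with overexpression. Other markers, chosen in the same way, did not. The antennal genes Pbprp5 and Os-E were lower with construct 1 (-2.07 and -1.91) and with overexpression (-1.59 and -1.57). They were not called with construct 2. Act88F, a flight muscle gene, was called higher with both constructs and with overexpression. The sarcomere list, higher with both constructs, was not called with overexpression. Markers thus did not oppose as a class. A different make-up of the tissue is still not separated from the excess of 273 genes.

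The dpp RNAi constructs differed from each other in 1283 genes, 605 higher and 678 lower with construct 1, of which 156 changed at least 2-fold. Cyp6a17, a cytochrome P450 gene, was at 39.4 ± 4.14 CPM with construct 1 and 1.79 ± 0.496 CPM with construct 2 (4.48 ± 0.15, adjusted p = 1.79e-12), against 45.3 ± 2.57 CPM in control RNAi and 53 ± 1.16 CPM in control. Cyp6a2 was at 40.1 ± 1.7 and 194 ± 3.93 CPM (-2.27 ± 0.05), and Cyp4p2 at 0.365 ± 0.123 and 13.2 ± 1.47 CPM (-5.09 ± 0.35). CCHa2 was at 138 ± 6.48 and 321 ± 7.38 CPM (-1.22 ± 0.06), and e at 55.9 ± 1.93 and 111.5 ± 15.4 CPM (-0.99 ± 0.10). Libraries did not overlap for 31.5% of tested genes, where chance gives 10%. The count fell to 827 without construct 1 replicate 2, to 682 without construct 1 replicate 3 and to 619 without construct 2 replicate 1.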

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

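The comparison of the photoreceptor with the sarcomere sums and the comparison with the control libraries were tests chosen after the results were seen. The photoreceptor, antennal, midgut and Hox genes and the neighbours of Cyp6a17 were chosen after values were seen, too.

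Photoreceptor transcripts were the most abundant in libraries whose label is skeletal muscle: the 13 genes of a photoreceptor list, with ninaE (a mean of 35170 CPM), Arr2 (15240 CPM) and Arr1 (11160 CPM) at its top, took 7.28 to 9.52% of TMM-scaled counts, and their sum was at least 3.39 times that of the 36 sarcomere genes in every library. The photoreceptor genes were picked for their high levels, so this comparison of sums cannot decide whether eye tissue was a small admixture to muscle. The median of the 13 genes was 1900 to 2690 CPM over the libraries. That of the sarcomere list, which was fixed before the data were examined, was 140 to 416 CPM. Of 5 flight muscle genes, fln had group means of 0.186 to 0.513 CPM, TpnC4 of 0.288 to 0.478 CPM and Act88F of 8.8 to 25.6 CPM. TpnC41C had group means of 18.2 to 112 CPM and Mf of 392 to 825 CPM. The 5 genes summed to between 413.1 and 1141 CPM over the libraries, and 8 brain neuropeptide genes to between 474.6 and 666.8 CPM. Muscle other than flight muscle was not tested in this way. A candidate explanation is that head tissue makes up most of the material: the abdominal Hox genes Ubx, abd-A and Abd-B summed to at most 0.0908 of the head Hox genes lab, pb, Dfd and Scr (0.278 to 7.67 CPM against 67 to 90.5 CPM), and the median of 9 antennal genes was 5.53 to 91.7 CPM against 0.0181 to 0.745 CPM for 8 midgut genes. No biological explanation was tested, since the design gives no group for it.

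Sarcomere genes and CheA and CheB genes were higher in both groups labelled dpp RNAi than in control RNAi, although a lower level of dpp was not detected. After thinning all libraries to the smallest gene count total, the sarcomere medians were 1.13 and 1.12. Thinning keeps each gene's expected share of its library, so the medians of such abundant genes could hardly change. It therefore cannot decide whether something that came with depth played a part. Against the control libraries the median was 0.12 with construct 2 and 0.05 with construct 1, in line with control RNAi standing apart from the other 4 groups, and Antp, the thoracic Hox gene, was at 2.96 ± 0.383 CPM in control RNAi and at least 1.69 times higher in each other group, so less thoracic tissue in the control RNAi libraries may account for part of it. Against this as a single cause, Antp was at 9.78 ± 0.251 CPM in control and 5 ± 0.514 CPM with overexpression, and the CheA and CheB median there was -1.35, while the sarcomere median was 0.00. An effect of the dpp RNAi constructs and a difference of batch or fly line between control RNAi and the rest stay open and cannot be told apart here, because the code block of control RNAi is its own.

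Differences between construct 1 and construct 2, seen in a test of the difference itself, reached 1283 genes, and 48 genes were called in opposite directions against control RNAi. Genes that differed at least 2-fold lay more often on arms 2R and 2L than tested genes matched for level. Of 146 runs of neighbours, 30.8% lay on 2R, where 21.2% was expected, and 25.3% on 2L, where 18.4% was expected. The permutation p for the largest excess of any arm was 0.012 (10000 draws), so the chromosome background of the fly lines may contribute. The same test gave 0.031 for construct 1 and 0.075 for construct 2 against control RNAi and 0.027 for overexpression. An uneven spread over arms was thus not special to this pair. For Cyp6a17, which lost 37.6 CPM from construct 1 to construct 2, the neighbouring paralogs Cyp6a22 and Cyp6a23 gained 0.656 of that, all of it in Cyp6a23 (73.4 to 98.5 CPM), so reads shared between paralogs could take part. Other Cyp6a genes rose as well, Cyp6a9 from 77.9 to 108 CPM, Cyp6a21 from 35.6 to 62.5 CPM and Cyp6a2 from 40.1 to 194 CPM, so a gain was not particular to the neighbours. A different action of the constructs, which the design names, was not tested apart from these.

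Of the other genes that differed most between the constructs, given as the log2 fold change of construct 1 against construct 2, the higher ones were Cyp6a17 at 4.48, AttA at 2.01, Lcp3 at 1.54, Obp83g at 1.44 and Ski6 at 1.14. The lower ones were Cyp4p2 at -5.09, phr at -3.22, ninaD at -2.56, Cyp6a2 at -2.27 and Jhedup at -1.85. Jhedup lost its call without construct 1 replicate 2 (-1.42) or 3 (-1.93) and without construct 2 replicate 1 (-1.59), 2 (-1.94) or 3 (-2.01). The share of reads not aligned, in the HTSeq summary lines, was 2.43, 2.12 and 6.5% in dpp overexpression replicates 1, 2 and 3, above the 1.22 to 1.69% of the control libraries.

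Other groupings of the same libraries were counted. For both constructs together, 1 of 100 splits (the real one, 1989 genes) reached the count, and the highest other was 1476 genes. The 2 other splits that kept control RNAi as the reference gave 1475 and 1476, while splits with 1 or 2 control RNAi libraries in the reference gave 0 and the 23 with none of them there gave 0 to 632. For opposite calls, 1 of 100 splits reached 418, the highest other being 157. Every other split of overexpression and control called 0 genes, so any pairing with one of those gave 0 by construction. This rank therefore cannot decide whether the opposite direction itself exceeds chance. For construct 1 (2643 genes, highest other 0), construct 2 (4358, highest other 0), overexpression (3002, highest other 0) and construct 1 against construct 2 (1247, highest other 0), the 10 splits are too few for a share under 0.05, and 1 of them was as large. For the gene lists the 10 splits are too few as well. There, 5 of 10 splits called at least as many as the real 8 with construct 1, the real one included (highest other 12). With construct 2, 5 of 10 called at least the real 12 (highest other 15), and with overexpression 10 of 10 called at least the real 5 (highest other 12). Other groupings of the same libraries thus called as many lists or more. The number of lists called at the preset correlation therefore does not set the real grouping apart.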

How the results depend on the processing

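No test in this part was chosen after the results were seen, except thinning and the use of the control libraries in place of control RNAi. With an adjusted p under 0.01, the calls numbered 1591 with construct 1, 2897 with construct 2, 1147 with both, 2079 with overexpression, 537 between the constructs and 196 in opposite directions. With a 2-fold minimum they numbered 444, 535, 284, 664, 156 and 63, in both cases by construction. With each library left out in turn, the ranges were 2024 to 2614, 3410 to 3995, 1489 to 1920, 2395 to 3463, 619 to 1243 (827, 682 and 619 being the values beyond 1.5 times, the cause was not tested) and 299 to 467, and dpp lay at 0.89 to 1.15 with overexpression, -0.03 to 0.10 with construct 1 and -0.07 to 0.07 with construct 2. The correlation of the constructs lay at 0.667 to 0.804 and that of both with overexpression at -0.089 to -0.048. After thinning, 2193, 3631, 1620, 2254, 1112 and 285 genes were called, so depth limits the counts. DESeq2 called 2823, 4377, 2102, 3274, 1483 and 459, and limma-voom 2606, 4340, 1978, 3411, 1091 and 428. Calls of lists went from 25 to 2 with the estimated correlation. With construct 1 it was 0.771 for oxidative phosphorylation and 0.508 for sarcomere genes, against the preset 0.01. The adjusted p-values of these lists at the preset thus treat correlated genes as nearly independent. The dopamine list with overexpression lost its call at an estimate of -0.033, so a correlation above the preset does not cover every lost call. Against control, 4 list calls were left with the estimated correlation, where 26 were made without it. Against control, 2621, 3858 and 1772 genes were called with construct 1, construct 2 and both, and 6 and 4 list directions were reversed; the cause was not tested. Leaving that last alternative aside, 277 of 411 called results of named genes lost the call in at least 1 alternative (256 with the 2-fold minimum), and none of 472 turned in sign. Against control, 30 named genes with construct 1 and 31 with construct 2 were called in the other direction, 29 and 40 in the same one, and 71 each were not called.

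With the replicate number as a block, the calls were 2747, 4415, 2031, 3138, 1429 and 406, and 8 named results lost and 1 gained a call. Residuals of samples with the same number correlated at 0.009, 0.02 and -0.035 (construct 1 with control RNAi), 0.069, 0.155 and -0.021 (construct 2) and 0.003, 0.06 and 0.186 (overexpression with control), and not every sample correlated best with its own number. Removing mitochondrial and rRNA genes moved nothing, since none of them was tested.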

Other observations

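The genes of this part, apart from Lst, were chosen after their values were seen, and no test of an explanation was run on them.

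Rh5, the blue-sensitive rhodopsin, was at 573 ± 20.3 CPM in control RNAi, 354 ± 21.1 CPM with construct 1 and 203 ± 17.3 CPM with construct 2 (-0.69 ± 0.07, adjusted p = 6.29e-06; -1.50 ± 0.07, adjusted p = 5.7e-10), with 224 ± 3.95 CPM in control, and it rose with overexpression to 331 ± 20.7 CPM (0.56 ± 0.07). With construct 2, Rh3, Rh4 and Rh6 fell as well (-0.52, -0.48 and -0.27), and against control Rh4 and Rh6 were lower with it (-0.32 and -0.23) while Rh3 was not called (0.04). With construct 1, Rh3 and Rh4 were also called lower (-0.27 and -0.26), but not without construct 1 replicate 1 (-0.22 each), nor Rh4 without control RNAi replicate 2 (-0.23), and against control Rh3 was higher (0.29, adjusted p = 0.00751). Rh6 was not called with construct 1 (-0.06). With overexpression Rh3 rose (0.31, adjusted p = 0.00353) and Rh4 was not called (-0.09). Rh6, the green-sensitive one, fell with overexpression from 1159 ± 57.9 to 686 ± 51.8 CPM (-0.76 ± 0.06, adjusted p = 2.24e-07). Against control, Rh5 was higher with construct 1 (0.66) and not called with construct 2 (-0.14).

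The antennal odorant-binding protein genes Pbprp5, Os-E and Pbprp2 were lower with overexpression than in control (-1.59, adjusted p = 0.018; -1.57, adjusted p = 0.034; -0.91, adjusted p = 1.4e-05) and lower with construct 1 than in control RNAi (-2.07, adjusted p = 0.00435; -1.91, adjusted p = 0.0148; -0.86, adjusted p = 9.02e-05). None of the 3 was called with construct 2 (-0.81, -0.80 and -0.24) or for construct 1 against control (0.45, 0.62 and 0.00). Against control they were higher with construct 2 (1.71, adjusted p = 0.00723; 1.73, adjusted p = 0.0164; 0.62, adjusted p = 0.000509), and control RNAi was higher than control in each (2.52, 2.53 and 0.86). Lst (CG8317), which encodes the peptide hormone limostatin, rose with overexpression (0.80 ± 0.07), fell with construct 1 (-0.83 ± 0.08) and was not called with construct 2 (-0.05 ± 0.08).

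In a principal component analysis of all libraries, the first component held 36.4% of the variance and set overexpression apart, and the second held 23.2% and set control RNAi apart.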
